A study of Mus musculus with 6 samples.

How the data were processed

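Total RNA was prepared from frozen tissue with a column kit that keeps small RNAs, labelled with cyanine 3-pCp and hybridised to Agilent mouse microRNA arrays of 1 colour, per the labels' protocols. The mice received 3E10 vector particles into a vein of the head on day 1 after birth, and tissue was taken at 6 months of age. The deposited values are on a log scale and came from RMA, a method of background correction, quantile normalization and summarisation over probes. The submitters' processing notes name RMA and limma without versions. The base of the logarithm is not stated and was taken as 2, the base RMA returns. Array medians of 6.39 to 6.44 and maxima of 14.42 to 14.82 fit that scale. The table held 695 rows, 1 per mature microRNA, 0 missing values, 0 control or viral rows and 0 columns of other series. Scanner files and detection calls were not analysed here, so no microRNA could be called present or absent, and rows near 6 may be background. No 2 arrays were identical. Ranked by brightness, miR-122 and miR-21 held the same places on every array, so quantile normalization of the deposited values sets their differences to 0 by construction and tests neither. The quantile normalization within RMA may likewise have narrowed the differences of these 2 in the deposited values.

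Samples were grouped by their labels into 3 liver tumours and 3 adjacent liver pieces. Labels tie each adjacent piece to a tumour, so that the numbers pair tissue of the same animal. The third tumour carries 1316 in its title and 1306 in its source label, and its adjacent piece is labelled 1316. Deviations from the group means correlated at -0.05, 0.07 and -0.003 within pairs 1293, 1309 and 1316, so the data themselves showed no pairing. No label says that the 3 tumours came from separate animals. If some shared an animal, p-values measure less than the spread between animals.

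All 695 microRNAs were tested with limma (version 3.58.1, R 4.3.3), lmFit and eBayes on the deposited log2 values, tumour against adjacent without a block, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Lists of 19 kinds were fixed before the data were examined, as were the design, the naming rule and the alternatives unless stated otherwise. Lists of at least 3 measured members, 17 in all, were tested with limma's camera at a preset correlation of 0.01, then with an estimated correlation and with fry, adjusted over the 17 lists. The 3 Dlk1-Dio3 lists pooled were tested apart, without adjustment. Differences between parts of the region were tested over the 3 pairs by exact sign flips. Lists overlap: 8 of the 47 microRNAs lowered in liver cancer are also stromal, 6 are hepatocyte, 6 belong to the miR-29 family, 4 to the miR-200 family and 3 to the leukocyte list. Of the list raised in liver cancer, 7 belong to the miR-17 cluster and its paralogs.

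Hairpins of the region were matched by symbol to the RefSeq annotation of GRCm38.p6, and all 53 matched. The annotation served only for names and order, and no coordinates are given because the sources used here name no genome build. It places miR-882 within the region, which was not on the lists. Its log2 fold change was -0.10 (limma adjusted p = 0.59). It was chosen after its values were seen.

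MicroRNAs named in the text follow 1 rule. It takes up to 12 higher and 12 lower microRNAs with the largest log2 fold changes among those called whose groups do not overlap, all members of the list in Rian, for each other list up to 4 called members or, with 0 called, the 2 largest changes, and miR-122 and miR-21 in any case. An asterisk marks the less abundant arm of a hairpin in the naming of the table.

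The fits were tested on simulated data, 50 sets of 695 microRNAs with 60 changed, picked at random. Noise was normal, independent between microRNAs and of the same spread in both groups, pooled from these arrays. For changes of 0.5, 1 and 2 on the log2 scale, 65.9%, 87.8% and 97.7% were recovered, and 0.49% of unchanged microRNAs were called. With the replicate block the recovered shares were 53.2%, 81.6% and 95.1%. In the data, the median SD among tumours was 2.85 times that among adjacent pieces, so these rates may not carry over. Alternatives were the replicate block, quantile normalization of the deposited values, centring on the median or the 75th percentile, filters on dim microRNAs, an intensity trend with robust eBayes, and leaving out each array or pair. Array weights, alone and with the block, were added after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.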

Results

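MicroRNA levels were measured on 1-colour microarrays in 3 liver tumours of C57BL/6J mice and in 3 pieces of normal-looking liver taken next to those tumours. The mice had received particles of an adeno-associated virus vector, AAV-Rian-CMV, for gene targeting at Rian, a maternally expressed non-coding RNA gene inside the imprinted Dlk1-Dio3 region. The deposited table held 1 log2 value for each of 695 mature mouse microRNAs on each of the 6 arrays. Array medians lay between 6.39 and 6.44, so most microRNAs were close to the lower end of the scale, while miR-122, the main microRNA of hepatocytes, averaged 14.80 ± 0.04 (SD, n = 3) in adjacent liver. Tumours and adjacent pieces carry the numbers 1293, 1309 and 1316, and each adjacent piece was labelled by the tumour it lay next to. The number of arrays limits the precision, and with 3 arrays per group an exact permutation test of a single microRNA cannot reach a two-sided p below 0.10.

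The first comparison asked which microRNAs differed between tumour and adjacent liver. The tumours held far more of a set of microRNAs from the Dlk1-Dio3 region. The largest difference was that of miR-154*, which averaged 10.97 ± 0.51 (SD, n = 3) in tumours and 6.45 ± 0.04 in adjacent liver, a log2 fold change of 4.52 ± 0.25 (SE), or 23.0-fold. Higher by 3.20 ± 0.19 and 3.15 ± 0.28 (SE) on the log2 scale were miR-376b and miR-410. Outside the region, the only calls in the fit of all 6 arrays were miR-92a, a member of the growth-promoting miR-17 cluster, which rose by 0.40 ± 0.07, and the epithelial microRNAs miR-200a and miR-200b, which fell by 0.63 ± 0.11 and 0.57 ± 0.10 on the log2 scale.

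In all, 20 of the 695 microRNAs passed an adjusted p of 0.05 in limma, 18 higher and 2 lower in tumours, and 41 higher and 98 lower had an unadjusted p below 0.05. For each of the 20, all 3 tumours lay beyond all 3 adjacent pieces. The groups separated in this way for 219 microRNAs, 31.5% of those tested, where chance gives 10% over both directions together. Most of these were lower in tumours: 159 (22.9% of those tested), against 60 higher (8.63%). Of the 18 that rose, 17 belonged to the Dlk1-Dio3 region. Adjacent liver gave means between 6.23 and 6.67 for the 17, near the median of 6.39 over all microRNAs, so their folds were understated on this scale wherever the adjacent signal was background.

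Besides the 3 already given, 9 region members made up the 12 largest rises among the called microRNAs. An uncalled member, miR-329, named after its values were seen, had a difference of 1.62 ± 0.33 (SE; limma adjusted p = 0.081), above that of miR-411*. Those of miR-495 (2.65 ± 0.17, SE), miR-300 (2.45 ± 0.20), miR-379 (2.39 ± 0.28), miR-377 (2.30 ± 0.20) and miR-299* (2.25 ± 0.23) exceeded 4-fold. The folds of miR-376a and miR-543 were 4.45 and 4.20, and those of miR-154 and miR-411* were 3.71 and 2.93. The 5 other called members of the region were miR-337-3p (0.52) and, named after their values were seen, miR-409-5p (1.04), miR-541 (0.98), miR-369-5p (0.79) and miR-381 (0.42). In limma without a block, adjusted p-values of the 12 ranged from 8.4e-04 for miR-154* and miR-376b to 0.015 for miR-376a. With the pair number as a replicate block, limma's adjusted p-values of the 12 ranged from 0.013, for miR-154* and miR-376b among others, to 0.055 for miR-376a. Mature sequences of the miR-376 family are nearly identical, so probes of miR-376a and miR-376b may read each other's targets, and how the signal splits between them is uncertain.

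**Figure D1:**
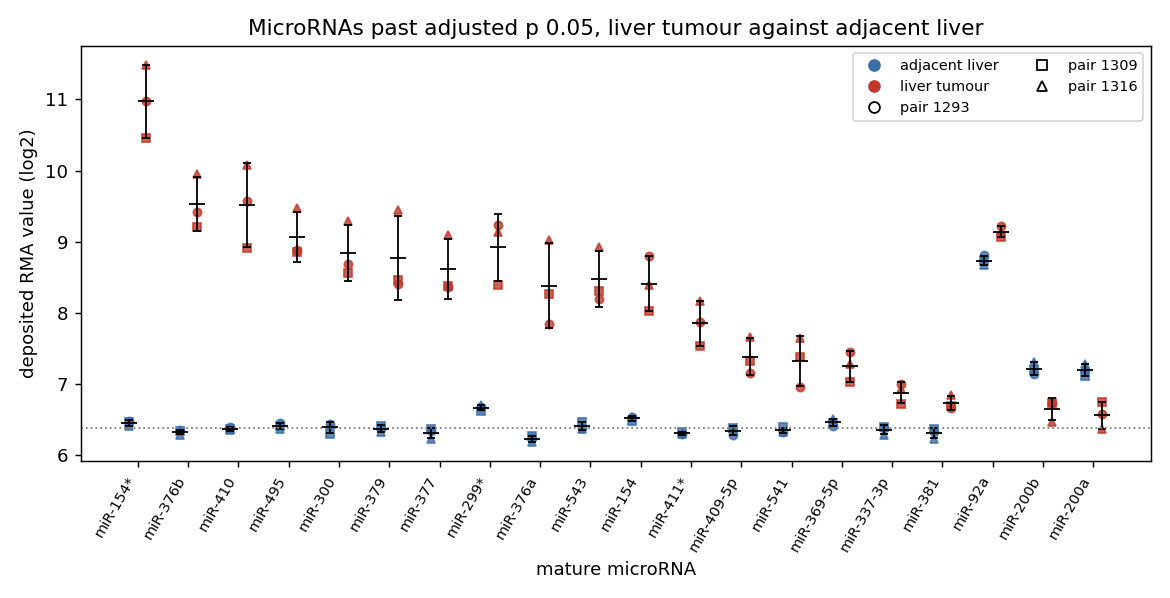
Deposited log2 values (vertical axis) of the 20 microRNAs past an adjusted p of 0.05, in adjacent liver (blue) and liver tumours (red); each symbol is 1 array, its shape gives the pair, black bars show mean ± SD (n = 3), and the dotted line marks the median of the adjacent means. The 18 microRNAs that rose and the 2 that fell show no overlap between groups.

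With the pair number as a replicate block, limma called 12 microRNAs, all higher, all in the Dlk1-Dio3 region and all among the 20, while 87 were lower at an unadjusted p below 0.05. The block ended the calls of miR-92a (adjusted p = 0.14), miR-200a and miR-200b (both 0.15) and miR-376a (0.055), and those of miR-337-3p, miR-369-5p, miR-381 and miR-541. The count depended on which arrays were used. Without tumour 1293, 19.6% of the 695 microRNAs were called (51 higher, 85 lower), against 2.88% with all arrays. Without pair 1293 the count was 56 (35 higher, 21 lower), and it was 58 without tumour 1309 (37 lower), 13 without tumour 1316, and 10 without any 1 of the adjacent arrays. Leaving out any 1 adjacent array ended the calls of miR-92a, miR-200a, miR-200b, miR-337-3p, miR-376a, miR-379, miR-409-5p, miR-541, miR-369-5p and miR-381. Leaving out tumour 1316 left 13 calls, and the first 4 of these microRNAs were among those lost. Quantile normalization of the deposited values left 16 calls. Those it ended included miR-92a (limma adjusted p = 0.055) and miR-337-3p (0.088). Among 19 alternatives, array weights included, miR-92a passed in 8, miR-337-3p in 9, miR-200a in 10 and miR-200b in 11. Without any 1 adjacent array, miR-379 stayed at 2.37 to 2.42 and miR-376a at 2.13 to 2.17 on the log2 scale, against 2.39 and 2.15 with all arrays. Fewer arrays give a test less power, so a call lost in this way need not mean dependence on 1 array.

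The second comparison concerned the Dlk1-Dio3 region itself, whose maternally expressed microRNAs lie before Rian, within it and after it, the last in the Mirg transcript. The table held 78 microRNAs of the region from 53 hairpins, and 66 of them had a higher mean in tumours. Their median log2 fold change was 0.28, with pair medians of 0.23, 0.25 and 0.36 in pairs 1293, 1309 and 1316. Over all microRNAs tested, 17 members were called higher and 0 lower by limma (36 and 1 at an unadjusted p below 0.05), and adjusted over the list alone 33 were higher and 0 lower. The region as a whole stood above the other microRNAs (camera p = 1.8e-30, two-sided; p = 0.0063 with an estimated correlation). Without tumour 1293, 42 members were called, without pair 1293 33, and without any 1 of the adjacent arrays 10.

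After Rian, 16 of the 54 measured microRNAs rose and 46 had a higher mean in tumours. Adjusted over the list alone, 29 of these 54 rose. Their median log2 fold change was 0.37 and their mean 0.83, since a minority of strongly raised members such as miR-154*, miR-376b, miR-410 and miR-495 stood above many small values. The list passed camera at the preset correlation (adjusted p = 2.7e-26) but not with an estimated correlation (adjusted p = 0.13). Among the alternatives with an estimated correlation, it passed camera only without tumour 1316 (adjusted p = 0.017). Camera's adjusted p with an estimated correlation was 0.44 under the replicate block, 0.45 without tumour 1293 and 0.57 without pair 1293. Without tumour 1293, 34 members were called, without pair 1293 30, and without any 1 of the adjacent arrays 10.

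Before Rian, only miR-337-3p among the 21 measured microRNAs passed limma's test over all microRNAs, rising by 0.52 ± 0.09 (SE) on the log2 scale. That call ended under the replicate block (adjusted p = 0.14). Adjusted over the list alone, 5 of the 21 rose: these were miR-337-3p and, named after their values were seen, miR-127 (0.60), miR-434-3p (0.50), miR-431 (0.35) and miR-433 (0.26). The median log2 fold change was 0.15 (camera adjusted p = 7.1e-05; adjusted p = 0.22 with an estimated correlation). The median was 0.09 without tumour 1293 and 0.05 without pair 1293, and 7 members were called without that tumour, 2 without that pair, 3 without tumour 1309, and 0 without tumour 1316 or any 1 of the adjacent arrays.

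The 3 microRNAs of Rian itself did not pass limma's test in the unweighted fit of all 6 arrays. Log2 fold changes were 0.23 ± 0.10 (SE) for miR-341, 0.26 ± 0.14 for miR-370 and 0.04 ± 0.05 for miR-1188, with limma adjusted p-values of 0.28, 0.36 and 0.68. All 3 averaged between 6.18 and 6.31 in adjacent liver and between 6.22 and 6.57 in tumours, near the lower end of the scale. Adjusted over the list alone, 0 of these were called, and 0 had an unadjusted p below 0.05. Camera gave the list an adjusted p of 0.0997, and an adjusted p of 0.51 with an estimated correlation. Without tumour 1293, miR-370 was called higher, by 0.42 on the log2 scale (limma adjusted p = 0.0027), and the list passed camera (adjusted p = 0.0099; adjusted p = 0.45 with an estimated correlation). Without pair 1293 these were 0.44 (limma adjusted p = 0.019) and a camera adjusted p of 0.012 (adjusted p = 0.57 with an estimated correlation). Without tumour 1316, miR-341 was at 0.13 and miR-370 at 0.17, and neither was called. With array weights, chosen after seeing the data, limma called miR-341 (0.32, adjusted p = 0.023) and miR-370 (0.41, adjusted p = 0.0029), and the list passed camera (adjusted p = 0.013; adjusted p = 0.30 with an estimated correlation). With the block added to the weights, miR-341 was no longer called (0.28, limma adjusted p = 0.097) and 1 member was. The list then passed camera (adjusted p = 0.016, and 0.47 with an estimated correlation).

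**Figure D2:**
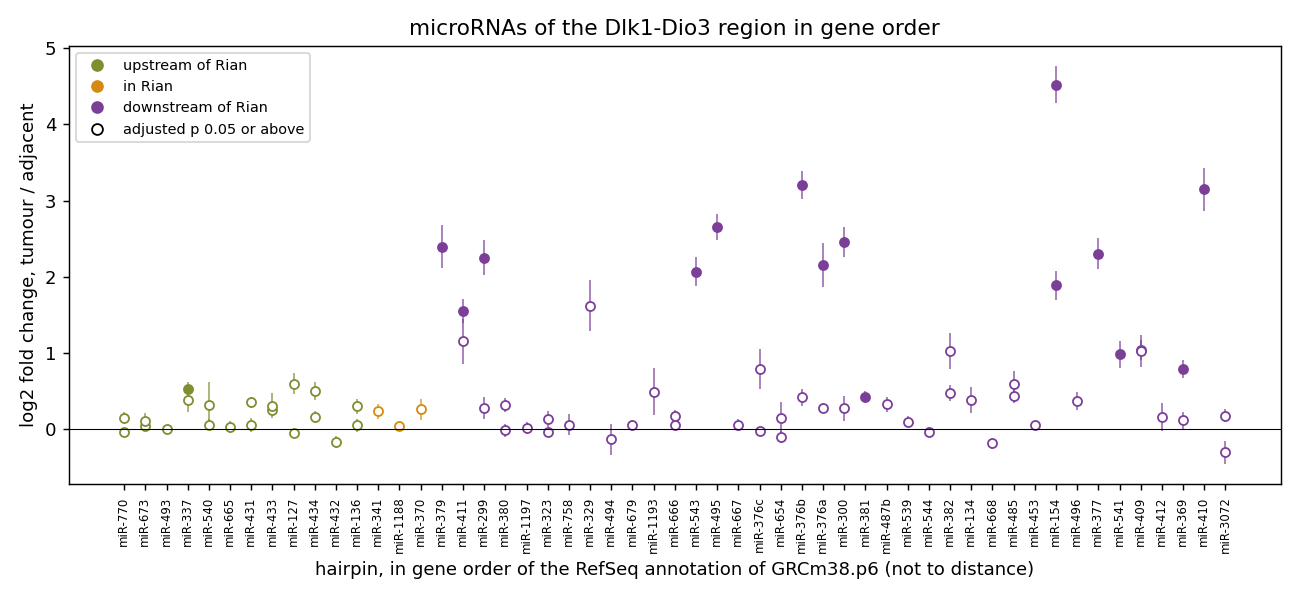
Log2 fold change of tumour over adjacent liver (vertical axis, bars ± SE) for the 78 microRNAs of the Dlk1-Dio3 region, at their 53 hairpins in the gene order of the RefSeq annotation of GRCm38.p6, not to distance (horizontal axis). Filled points passed a limma adjusted p of 0.05: 1 before Rian, 0 in it and 16 after it.

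Members after Rian gained more than members before it in each of the 3 pairs. The mean difference between these lists was 0.52, 0.60 and 0.80 on the log2 scale in pairs 1293, 1309 and 1316, or 0.64 ± 0.14 (SD, n = 3 pairs). The exact sign-flip permutation test gave p = 0.25, two-sided, the smallest value that 3 pairs allow. Taking list medians in place of means, the difference was 0.27 ± 0.16 (SD, n = 3 pairs). Members after Rian also exceeded those in Rian, by 0.64 ± 0.10 (SD, n = 3 pairs; exact permutation p = 0.25) from means and by 0.20 ± 0.09 from medians. The lists in and before Rian differed by -0.01 ± 0.18 from means (exact permutation p = 1) and by 0.07 ± 0.25 from medians (exact permutation p = 0.75).

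The third comparison took 16 further lists of microRNAs, of which 14 had enough members for a test. MicroRNAs typical of hepatocytes, those often described as lowered in liver cancer, and the miR-30 family had lower values in tumours as lists, while few of their members passed singly. The hepatocyte list had a median log2 fold change of -0.47, and 14 of its 16 members had a lower mean in tumours. The miR-30 family, abundant in differentiated epithelia, had a median of -0.39, and all 10 members had a lower mean. The list of microRNAs lowered in liver cancer had a median of -0.21, with 34 of 47 lower. For comparison, 59.6% of all 695 microRNAs had a lower mean in tumours. Outside the region, so did 90.7% of the 172 microRNAs brightest in adjacent liver (median -0.32). Camera set each list against all other microRNAs, most of them near the lower end of the scale. It could therefore not part a trend with brightness from a change of these lists.

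Camera's adjusted p was 0.0092 for the hepatocyte list, 6.6e-04 for the miR-30 family and 4.0e-04 for the list lowered in liver cancer. With an estimated correlation, none of these calls held (adjusted p = 0.51, 0.51 and 0.38). Adjusted over the list alone, 7 hepatocyte microRNAs were lower and 1 higher (miR-193b, 0.50, named after its value was seen), 7 of the miR-30 family were lower, and 11 of those lowered in liver cancer were lower. Over all microRNAs tested, no hepatocyte or miR-30 member was called by limma (8 lower in each list and 1 hepatocyte member higher at an unadjusted p below 0.05), and miR-200a and miR-200b were the 2 called members of the liver cancer list. The largest hepatocyte differences were those of miR-101a (-1.19 ± 0.37, SE; limma adjusted p = 0.15) and miR-194 (-0.76 ± 0.21; adjusted p = 0.12), and in the miR-30 family those of miR-30a* and miR-30d (both -0.70). For miR-122 the difference was -0.11 ± 0.12 (SE; limma adjusted p = 0.66), and 0.02 without tumour 1316. As the brightest microRNA on every array, miR-122 may be held near the array maximum by the quantile normalization in RMA, so its small difference says little. Tumour 1293 held the largest differences in both lists, with list medians of -0.60 for hepatocytes and -0.56 for miR-30, against -0.24 and -0.23 in pair 1309 and -0.41 and -0.37 in pair 1316. Without that tumour, miR-101a was at -0.77 and miR-30a* and miR-30d both at -0.44. Without tumour 1293, limma called 7 hepatocyte members lower and 1 higher, 8 of the miR-30 family lower, and 21 of the liver cancer list lower and 1 higher, whereas without pair 1293 it called 1, 4 and 9 lower in these lists and 0 higher. Without tumour 1309 it called 8 lower and 1 higher, 2 lower, and 12 lower in these 3 lists, and without tumour 1316 the hepatocyte list no longer passed camera (adjusted p = 0.051). Over members with a mean above the median of all microRNAs, the liver cancer list had a median of -0.44.

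Markers of other cell types also had lower medians in tumours. In the miR-200 family, found in bile duct and other epithelia, 2 of 9 members fell and the list median was -0.16 (camera adjusted p = 0.084). The stromal list of fibroblast, stellate and smooth muscle cells had a median of -0.15 (adjusted p = 0.30), with values of -0.85 ± 0.18 (SE) for miR-199a-3p and -0.58 ± 0.17 for miR-143. The leukocyte list had a median of -0.18 (adjusted p = 0.52), led by miR-146a (-0.59) and miR-223 (-0.45). Muscle and neural lists, for cells not usual in liver, had medians of -0.09 and -0.05 (adjusted p = 0.30 and 0.78). Only 6 of the 7 muscle entries were matched, since miR-1 carries a different name in the data and was left out. No stromal, leukocyte, muscle or neural member passed limma's test over all microRNAs, where 3 stromal, 2 leukocyte, 0 muscle and 0 neural members were lower at an unadjusted p below 0.05. Adjusted over the list alone, miR-200a, miR-200b, miR-429 (-0.40, named after its value was seen) and the stromal miR-199a-3p were lower, and 0 members of the leukocyte, muscle and neural lists were called. The endothelial and erythroid lists held 2 measured microRNAs each and were not tested. Their values were -0.12 for miR-126-3p and -0.39 for miR-126-5p, and -0.16 for miR-451 and -0.46 for miR-144. Without tumour 1293 the medians were -0.06 for leukocyte, -0.03 for muscle, -0.02 for neural and -0.12 for erythroid microRNAs, and single values were -0.34 for miR-146a, -0.25 for miR-223, -0.38 for miR-143, -0.22 for miR-126-5p, -0.20 for miR-144 and -0.05 for miR-451. In that setting limma called 5 stromal, 3 miR-200, 1 leukocyte and 1 endothelial member lower, and the stromal and miR-200 lists passed camera (adjusted p = 0.0068 and 0.035; adjusted p = 0.45 and 0.53 with an estimated correlation). Without pair 1293, 5 stromal, 1 miR-200, 0 leukocyte and 0 endothelial members were called lower, the stromal list passed camera (adjusted p = 0.0042; adjusted p = 0.57 with an estimated correlation), and the miR-200 list did not (adjusted p = 0.081). The miR-200 list also passed without the adjacent piece 1309 (adjusted p = 0.029; adjusted p = 0.51 with an estimated correlation) and over its 4 members with a mean above the median of all microRNAs (median -0.48; adjusted p = 0.041, and 0.55 with an estimated correlation). The stromal miR-199a-3p was called without tumour 1309, miR-126-3p was at 0.11 after quantile normalization of the deposited values, and miR-451 was at 0.13 without the adjacent piece 1316.

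Among families linked to growth, only miR-92a was called of the 20 measured members of the miR-17 cluster and its paralogs, also adjusted over the list alone, and the list median was 0.02 (camera adjusted p = 0.32). The list of microRNAs often described as raised in liver cancer had a median of -0.02 (adjusted p = 0.91), and 0 of its 25 members were called by limma, over all microRNAs or adjusted over the list alone (2 higher and 3 lower at an unadjusted p below 0.05). Within it, miR-21, a microRNA raised in many cancers, had a value of 0.50 ± 0.17 (SE; limma adjusted p = 0.17), and miR-151-5p one of -0.98 ± 0.30 (adjusted p = 0.15). The let-7 family, known for growth-restraining targets, had a median of -0.23 (adjusted p = 0.15), with 0 members called by limma over all microRNAs, 7 lower at an unadjusted p below 0.05, and 6 lower adjusted over the list alone. Its members went both ways, let-7e at -0.79 ± 0.24 (SE) and let-7d* at 0.80 ± 0.68, the latter through tumour 1293 alone, where it read 8.95 against at most 6.55 on the other arrays. Without that tumour, let-7d* was at -0.03, let-7e at -0.51 and miR-151-5p at -0.63. The median of the miR-17 list was -0.02 with 75th percentile centring, and that of the let-7 family -0.10 after quantile normalization of the deposited values. Without tumour 1293, 5 members of the miR-17 list were called higher and 2 lower, 2 of the list raised in liver cancer higher and 4 lower, and 4 let-7 members lower, and the miR-17 and let-7 lists passed camera (adjusted p = 0.018 and 0.0099; adjusted p = 0.45 and 0.47 with an estimated correlation). Without pair 1293, 2 members of the miR-17 list were called higher and 0 lower, and 0 of the list raised in liver cancer and of the let-7 family, while camera gave the miR-17 and let-7 lists adjusted p = 0.013 and 0.016 (adjusted p = 0.57 and 0.64 with an estimated correlation). Without tumour 1309, 2 of the list raised in liver cancer and 3 let-7 members were called lower.

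The miR-29 family had a median of -0.01 (camera adjusted p = 0.79), with miR-29c at -0.40 (-0.17 after quantile normalization of the deposited values) and miR-29b-1* at -0.13 (-0.07 without tumour 1293). It had 1 member called higher without tumour 1293 and 0 without pair 1293, and miR-29c was called lower without tumour 1309. Other imprinted or clustered microRNAs showed no call in limma. The list of the H19 and Igf2 genes had a median of -0.01 (adjusted p = 0.79), with miR-675-3p at 0.47 ± 0.32 (SE) and miR-483 at -0.11, which were 0.08 and -0.02 without tumour 1293. The 41 measured members of the Sfmbt2 cluster, many of them nearly identical, had a median of -0.03 (adjusted p = 0.72), the largest differences being 0.23 for miR-467d* and 0.17 for miR-297a*, which were -0.03 and 7.6e-05 without tumour 1293. The median of the H19 and Igf2 list was 0.02 after quantile normalization of the deposited values. Adjusted over the list alone, 0 members of the miR-29, H19 and Igf2, and Sfmbt2 lists were called, and 1, 0 and 1 were lower at an unadjusted p below 0.05. Without tumour 1293, 7 of the 14 lists outside the region passed camera in place of 3, and 0 did with an estimated correlation (lowest adjusted p = 0.45). Without pair 1293, 6 passed, and 0 with an estimated correlation (lowest adjusted p = 0.57).

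**Figure D3:**
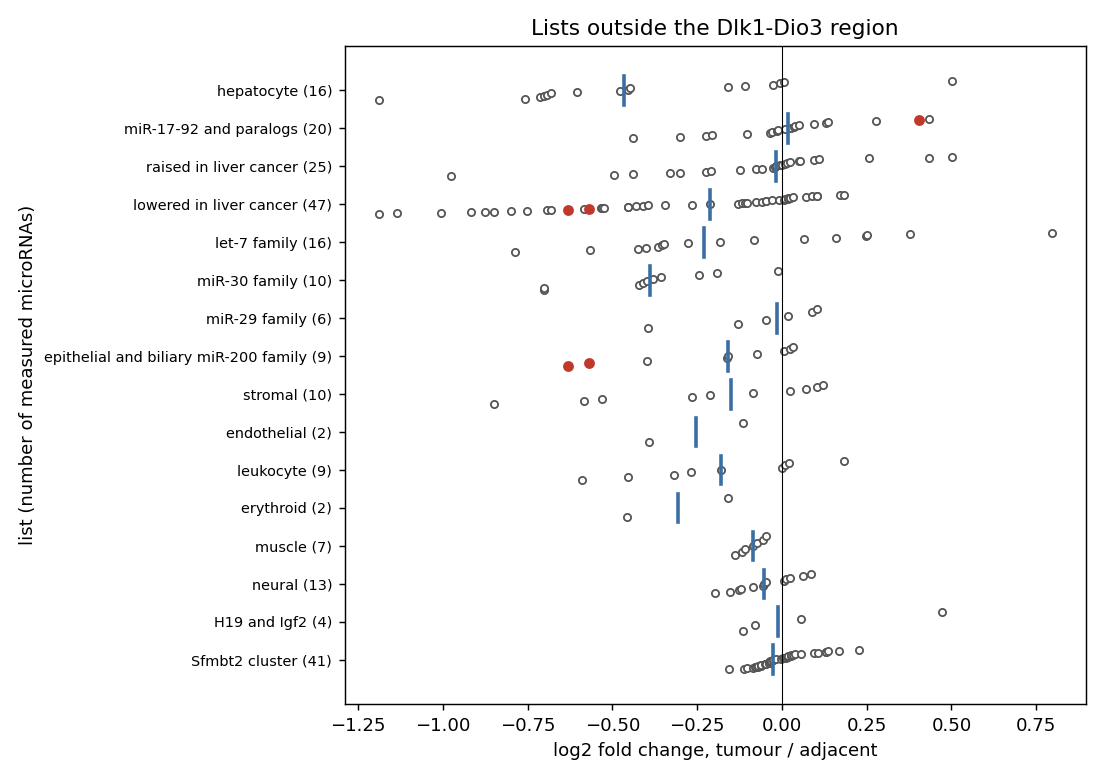
Log2 fold change of tumour over adjacent liver (horizontal axis) for each measured microRNA of the 16 lists outside the Dlk1-Dio3 region (vertical axis, number of members in brackets); blue bars are list medians and red points passed a limma adjusted p of 0.05. Most hepatocyte and miR-30 members lie below 0, while 3 microRNAs pass singly.

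The last comparison asked how alike the 3 tumours were. Adjacent pieces were nearly identical, with correlations across microRNAs of 0.995 to 0.996, where microRNAs are not independent replicates. Tumours correlated with one another at 0.888 to 0.982, tumours 1309 and 1316 most closely, and with adjacent pieces at 0.803 to 0.940. The median SD over microRNAs was 0.14 among tumours and 0.05 among adjacent pieces, a ratio of 2.85, and 83.9% of microRNAs varied more among tumours. Without pair 1293 the ratio was 1.26, and with 2 tumours against all 3 adjacent pieces, leaving out tumour 1293 alone, it was 0.99. The median SD of 2 arrays tends to lie below that of 3, so 0.99 does not show equal spread.

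**Figure D4:**
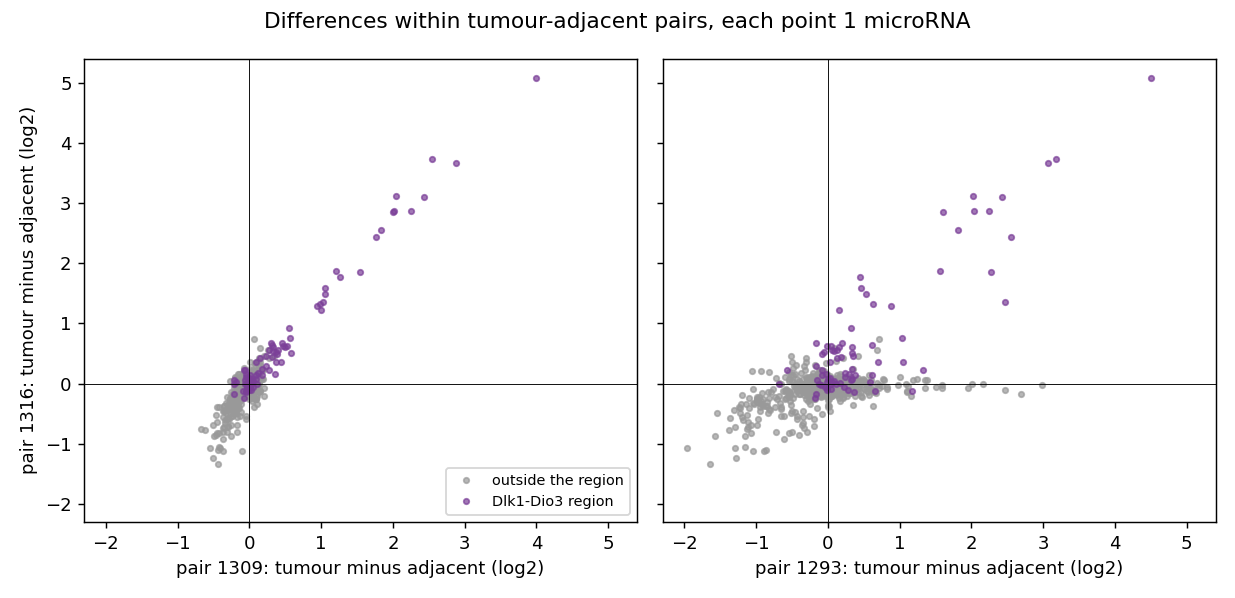
Tumour minus adjacent difference on the log2 scale of each microRNA in pair 1316 (vertical axes) against pair 1309 (left) and pair 1293 (right); purple points are the 78 microRNAs of the Dlk1-Dio3 region and grey points all others. Across microRNAs the differences correlate at 0.95 between pairs 1309 and 1316 and at 0.66 between pairs 1293 and 1316.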

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

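No result changed direction past its threshold under any alternative. Array weights were chosen after seeing the data, and the cause of each change was not tested unless stated. The pair number as a replicate block called 1.73% of microRNAs (0 lower) in place of 2.88% and, besides the calls of single microRNAs, changed no other call. Scalings, filters and the intensity trend gave 16 to 20 calls, the trend with 0 lower. Array weights called 19.9% (51 higher, 87 lower; 44 in the region), and with the block 10.5% (38 higher, 35 lower; 36 in the region). Leaving out 1 array or pair called 1.29% to 19.6%, with 8 to 51 higher, 0 to 85 lower, and 8 to 42 in the region; the highest values came without tumour 1293. The ratio of spreads was 4.98 among the brighter microRNAs and 0.99 to 3.94 with 1 array or pair left out (1.26 without pair 1293). Where 1 array was left out, the groups differed in size, which shifts the ratio. The region median stayed above 0, and its camera p past the threshold, under all alternatives. Filters on the mean over all 6 arrays say nothing about the size of the region medians, because a rise in tumours lifts dim members over the limit: 21 of the 44 members above the median lay at or below it in adjacent liver. Before Rian the median was 0.05 to 0.20 with arrays left out and 0.07 with array weights and the block. The gap between members after and before Rian was 0.27 from medians and 0.56 to 0.70 with a pair left out. The list in Rian was not called after adjustment over the lists (adjusted p = 0.0997). Its unadjusted camera p, 0.041 at a median of 0.23, was above 0.05 at a median of 0.22 (median centring) and 0.25 (centring outside the region), nor at 0.23 with fry (p = 0.075) or an estimated correlation (p = 0.17); the median ranged from 0.13 to 0.30 with arrays left out, and the p was above 0.05 without tumour 1309 (p = 0.10), tumour 1316 (0.11), the adjacent piece 1316 (0.072), pair 1309 (0.096) or pair 1316 (0.17). Outside the region, 3 lists passed camera, 7 with array weights, 5 with these and the block, 2 to 7 with arrays left out, 0 with an estimated correlation and 1 by fry (lowered in liver cancer). Of the 16 named microRNAs that were called, miR-154*, miR-300, miR-376b, miR-410 and miR-495 passed under every alternative. For the other lists 269 outcomes were the same, 7 weaker and 15 stronger; for named microRNAs 774, 52 and 40. The smallest p of 3 pairs and of 3 against 3 arrays, and the signal near background of most microRNAs, limit what can be tested.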

Other observations

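All tests in this part were chosen after the results had been seen. Several microRNAs were high on the array of tumour 1293 alone, and those named here were chosen after their values were seen. On that array miR-1894-5p read 9.45 and miR-211 read 9.30, where the highest of the other 5 arrays read 6.46 and 6.64. Likewise let-7d* (8.95), miR-1196 (8.61), miR-328 (8.72) and miR-204 (8.45) stayed at or below 6.77 on the other arrays. With 1 tumour showing them, these differences had no replicate check.

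Among the 16 hairpins after Rian with both arms measured, the median absolute difference between arms in log2 fold change was 0.52 and the largest 2.79, for miR-376b (3.20) and its other arm (0.42). For miR-154 the arms were higher by 4.52 and 1.89, and for miR-409 by 1.04 and 1.03. In adjacent liver miR-376b averaged 6.33, near the median of 6.39 over all microRNAs. Folds are understated wherever the adjacent signal was background, so differences between arms are not exact.

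Of the 10 splits of the 6 arrays into 3 and 3, 1 gave 20 calls, the real one, and the highest of the others gave 0, including the other 3 that part all pairs. For the region median the count was again 1, with 0.28 for the real split and 0.12 as the highest other in size. For lists outside the region, 3 of the 10 splits gave at least the real number of 3, and the highest other gave 4. With 10 splits the share cannot fall below 0.05, so these counts do not settle whether chance grouped the arrays. The split with 4 lists parts all pairs and sets tumours 1293 and 1316 with the adjacent piece 1309 against the rest.

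Members after Rian gained more than those before or in it. Probes that miss gains at random, each hairpin independent of the others, are argued against. Relabelling hairpins gave a gap as large as the observed 0.65 with p = 0.00137 (one-sided permutation test, 38 against 15 hairpins). That test treats neighbouring hairpins as independent, so it cannot speak to misses shared between neighbours. Its p does not measure the spread between tumours, for which the exact sign-flip test over pairs gave p = 0.25. Weaker probes for the members before and in Rian may still account for it: their median adjacent level differed by only -0.0624 from that of the members after it, but 0 of the 24 were bright in adjacent liver, so their sensitivity cannot be judged. A gain that falls with distance from Rian was not seen and stays open, since gene order stood in for distance. Over the 38 hairpins after Rian, Spearman rho between order and the higher arm's log2 fold change was 0.0927 (permutation p = 0.58). As a hypothesis, targeting at Rian may act mainly on transcription beyond Rian, which these data cannot test without vector positions.

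Tumour 1293 stood apart, with 27 of 294 dim microRNAs outside the region higher by more than 0.5 in its pair and 0 in the others. A mislabelled adjacent piece is argued against, because its members after Rian exceeded its adjacent piece by 0.755 on average, where adjacent arrays differed by at most 0.013. RNA of the 7 listed other cell types stays open: the highest list median in pair 1293 was 0.0219, for the stromal list, with an SD of 0.608 over members that went both ways, and 2 of the 52 microRNAs on these lists were higher by more than 0.5. Such RNA, cells outside those lists, lower RNA or array quality, and a true difference between tumours may each account for it and cannot be told apart here, since no quality measure was analysed.

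Bright microRNAs outside the region, those above 6.72 in adjacent liver whatever their tumour level, were lower in tumours. Their median was -0.324 over 172 microRNAs, 156 of them lower. Medians were -0.538, -0.180 and -0.255 in pairs 1293, 1309 and 1316, where 99, 5 and 41 were below -0.5. The cut on the adjacent level left out microRNAs bright in tumours alone, which can tilt these values downward. Over microRNAs with a mean of all 6 arrays above the median, region included, the median was -0.10. A shift tied to brightness alone is argued against for the differences among the 172 bright microRNAs, as these correlated between pairs 1309 and 1316 at 0.799 after the trend with brightness was removed (across microRNAs; permutation p = 1e-05, the smallest possible), though at 0.386 and 0.446 between pair 1293 and these. For the median itself such a shift could not be excluded. With that shift open, neither a lower share of hepatocytes (7 lists of other cell types with medians of at most -0.0527, and 16 of 52 members with a higher mean) nor fewer cells of other types (hepatocyte list at -0.466, SD over pairs 0.178) could be excluded. A change of liver microRNAs in the tumour cells remains a candidate explanation too and was not tested.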
